A study of Mus musculus with 9 samples.

How the data were processed

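Total RNA from mouse striatum was measured on 9 single-colour arrays, 3 for each of 3 groups. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit, and biotinylated cDNA was made from 200 ng of it with the Ambion WT Expression kit and the standard Affymetrix procedure. The deposited values are log2 intensities of summarised probe sets, and their scale was read from the values themselves: each array runs from about 4.27 to between 14.07 and 14.43, with a median between 6.85 and 6.90. The method of background correction, normalization and summary is not given in the sources used here. Whether the authors applied any other step is likewise not given, so the values were used as deposited, without further scaling. The quartiles were alike on all arrays (lower 5.57 to 5.67, upper 8.60 to 8.69). The number of arrays limits the precision of each comparison.

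Samples were grouped by the titles and source names in the labels: saline control, acute MPTP and chronic MPTP. Probe sets were named through the platform annotation. Of 28815 probe sets, 21780 had 1 gene symbol, 1605 had several and 5430 had none in that annotation. The gene identifiers of 21689 of the 21780 were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. The table was used for names only, and no genome build is named for the values. Probe sets with 1 symbol and a mean over the 9 arrays at or above the 25th percentile (log2 5.89) were tested: 16335 probe sets of 14880 genes. Of these genes, 809 had more than 1 probe set tested, up to 36. Single genes were tested by probe set; for gene lists the probe set with the highest mean over all arrays stood for its gene. Of 181 symbols named under the rule below, 4 had several tested probe sets; those of Tns1 differed in sign in all 3 comparisons and those of Arpc1b in the chronic against control comparison.

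All tests used limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to the log2 values of all 9 arrays, which left 6 residual degrees of freedom per probe set before moderation by eBayes. The comparisons were acute MPTP against control, chronic MPTP against control, and chronic against acute MPTP. Tests were two-sided, with Benjamini-Hochberg adjustment over the 16335 probe sets of each comparison and a threshold of 0.05. Counts of probe sets at 1.5-fold with an unadjusted p under 0.05 are given as descriptions. Errors beside log2 fold changes are standard errors of that fit with 3 arrays per group, and errors beside group means are standard deviations. Differences of Nxph3 also had an exact permutation test, which with 3 arrays against 3 cannot go below 0.1.

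The 27 gene lists, of cell types, neighbouring brain regions and pathways, held 517 genes, of which 474 had a probe set with 1 symbol and 445 were tested. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of each comparison, with camera at a correlation estimated from the data and with fry beside it. Fry asks whether the genes of a list move one way on balance, or in its mixed form in either direction, without setting them against other genes. Members were also adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined.

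Under that rule the genes named in each comparison were, in each direction, up to 10 probe sets past the threshold whose groups did not overlap, filled to 8 by the smallest unadjusted p among non-overlapping probe sets with a change of at least 1.3-fold where fewer than 5 passed. Genes without a proper symbol were left unnamed. Named in addition were the neurexophilins, Th, Slc6a3, Slc18a2, Ddc, Drd1, Drd2, Penk, Tac1, Pdyn, Gfap, Aif1 and Fos, list members past the threshold over all genes or over the list alone, or the 2 with the smallest p where a list had none, and up to 4 members of each called list.

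The replicate numbers in the sample titles were checked for pairing before the fits were compared. Deviations from the group means correlated between same-numbered arrays of different groups in all 9 pairs (r from 0.157 to 0.673, across probe sets). The 18 pairs with different numbers had r from -0.609 to 0.184, and 9 of 9 arrays were closest to an array of their own number. The numbers therefore count as pairing the samples, from the values and not from a statement in the labels, and a fit with the replicate number as a block (4 residual degrees of freedom) was run beside each test. No 2 arrays held the same values: at most 4.51% of values were identical between any 2 arrays.

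The code was tested on simulated data in the acute against control layout, with 200 of 16335 probe sets changed in each of 20 draws of independent noise. It called 49.7% of probe sets changed 1.5-fold, 90.3% of those changed 2-fold and 99.1% of those changed 3-fold, and 5.25% of its calls were unchanged probe sets. A list shifted by 0.3 on the log2 scale was called in 100% of draws, and 0.2% of tests of unshifted lists were calls. The draws held no correlation between genes and no pairing of samples. These rates therefore check the code only and do not carry over to the real lists, whose estimated correlation reached 0.65.

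Alternatives were quantile normalization, centring on array medians, no filter and a filter at the 50th percentile, a trended and robust variance model, only the 2 groups compared, array weights, the replicate block, an adjusted p under 0.10, the mean of a gene's probe sets, the estimated correlation, and each array left out in turn. After the data were seen, 4 more were added: the means of the lists of cerebral cortex genes and of thalamus, septum and hypothalamus genes as covariates, without and with the replicate block, and fits without 3 arrays high in cortex genes or without 2 arrays high in choroid plexus genes. Apart from the alternative with the estimated correlation, every alternative tested lists in camera with the preset correlation. Shared controls were simulated in 100 draws with the spread of the fit without the block and, chosen after the data were seen, with that of the blocked fit and with lists of the real lengths. Probe sets with several symbols or none, and those under the filter, were left out of the comparisons.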

Results

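Gene expression in mouse striatum was measured after treatment with MPTP, a compound whose metabolite enters dopamine neurons through the dopamine transporter and inhibits respiratory complex I. The axons of those neurons end in the striatum, which is made up largely of projection neurons carrying dopamine receptors. In the acute group MPTP was injected 4 times, 2 h apart, at 20 mg/kg, and the tissue was taken 1 week later. The chronic group was given 4 mg/kg per day for 20 days and was sampled after 8 weeks. The total dose was 80 mg/kg in both. Controls received 4 injections of saline 2 h apart and were sampled after 1 week, so chronic MPTP differed from both other groups in regimen and in time together. Each group had 3 arrays. The labels do not tie each array to a separate animal, so p-values measure the spread between these samples, which need not be a spread between animals. The title of the series concerns neurexophilin 3 and progenitors of dopamine neurons derived from pluripotent stem cells, and the arrays ask which striatal transcripts differ after each regimen.

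Genes of neighbouring tissue varied widely between arrays. Tbr1, a transcription factor of cortical glutamatergic neurons, lay at log2 9.89 on control 1, 9.12 on acute 1 and 9.65 on acute 2, against 5.69 to 7.26 on the other 6 arrays. Slc17a7, the vesicular glutamate transporter of cortex, lay between 11.75 and 12.28 on those 3 arrays and between 8.14 and 9.66 elsewhere. Ttr, the main secreted product of choroid plexus, reached 12.56 on control 3 and 13.37 on acute 3, against 6.19 to 10.85 elsewhere. Slc17a6, the vesicular glutamate transporter of thalamus and hypothalamus, lay at 10.59 and 9.44 on the same 2 arrays and between 6.42 and 8.51 on the rest. The 3 arrays high in cortex genes were 1 control and 2 acute arrays, and no chronic array was among them. Within the control, acute and chronic groups Ttr ran from 6.19 to 12.56, 7.38 to 13.37 and 7.38 to 10.85. Slc17a6 ran from 7.19 to 10.59, 6.54 to 9.44 and 6.42 to 8.51. These spreads argue against the arrays of a group being repeats of 1 RNA sample. Whether they came from separate animals is not given.

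**Figure D1:**
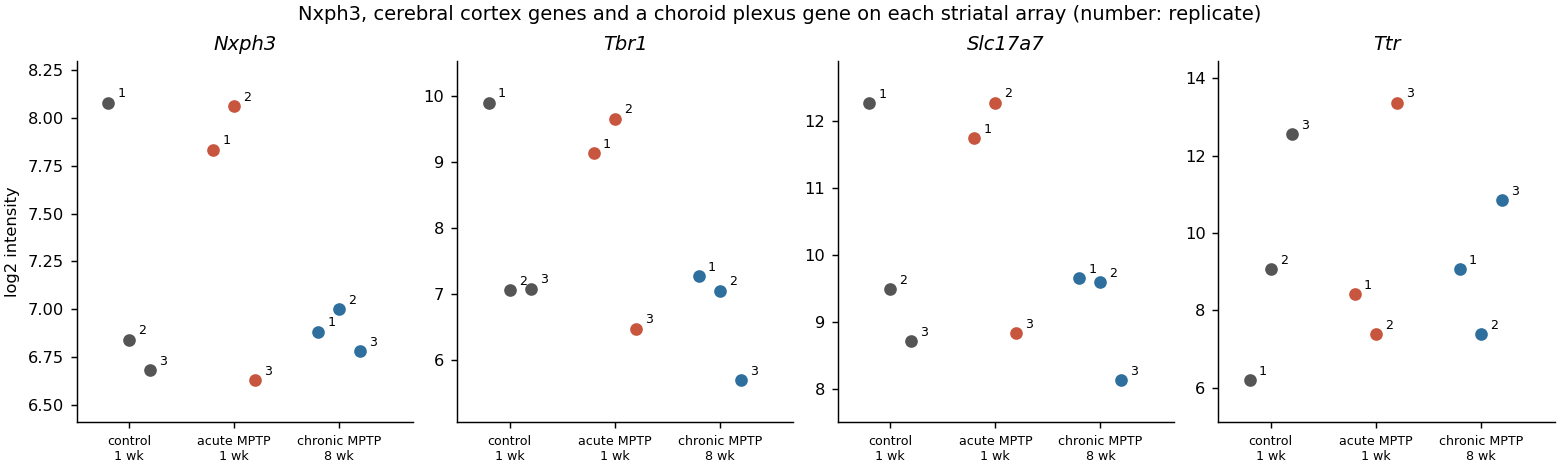
Log2 intensity of Nxph3, of the cortex genes Tbr1 and Slc17a7 and of the choroid plexus gene Ttr on each of the 9 arrays, by group, with points numbered by replicate. Nxph3, Tbr1 and Slc17a7 are high on control 1, acute 1 and acute 2, while Ttr is highest on control 3 and acute 3.

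Nxph3, a secreted ligand of alpha-neurexins, did not differ between the groups by more than its spread within them. Its log2 intensity was 8.08, 6.84 and 6.68 on the control arrays, 7.83, 8.06 and 6.63 on the acute arrays and 6.88, 6.999 and 6.78 on the chronic arrays. The log2 fold change was 0.31 ± 0.42 for acute against control (exact permutation p = 1, adjusted p = 1 in limma). It was -0.31 ± 0.42 for chronic against control (exact permutation p = 0.9, adjusted p = 0.974) and -0.62 ± 0.42 for chronic against acute (exact permutation p = 0.4, adjusted p = 0.878). With 3 arrays against 3 the exact test cannot go below 0.1. The 3 arrays high in Nxph3 were those high in Tbr1 and Slc17a7. With the means of the 2 tissue lists as covariates the differences were 0.03 (95% interval -0.19 to 0.25), 0.14 (-0.16 to 0.44) and 0.11 (-0.17 to 0.40), and the second and the third of them turned in sign. Chronic against control also turned without control 1, to 0.13, and was -0.49 and -0.57 without control 2 and control 3. Acute against control was 0.75, 0.13 and 0.05 without control 1, 2 and 3 and 0.14, 0.03 and 0.75 without acute 1, 2 and 3, and chronic against acute was -0.34 without acute 2 and -1.06 without acute 3. The related Nxph1 and Nxph4 had log2 fold changes of -0.21 and -0.02 for acute against control and of -0.21 and -0.17 for chronic against control; with the tissue covariates they were 0.02 and -0.07, and 0.17 and 0.03. Without control 3 Nxph1 turned to 0.08 and 0.08, and in acute against control Nxph4 ran from -0.16 without acute 2 to 0.11 without acute 3. Nxph2 lay below the filter, with a mean of 5.30. The list of neurexophilins and neurexins passed in 0 of the 3 comparisons, though with the tissue covariates it did in chronic against acute MPTP (0.11, adjusted p = 0.0344). Without the 3 arrays high in cortex genes, which leaves 1 acute array, its median was -0.13 in acute against control. Of its 5 tested genes 0 passed adjusted over the list alone.

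At 1 week after acute MPTP, 15 of 19 tested immediate early genes, which neurons transcribe soon after stimulation, were lower than in the controls. Their list passed in camera with the preset correlation but not with an estimated one (adjusted p = 0.275). Nr4a1, a nuclear receptor of this class, lay at 8.66 ± 0.07 (SD, n = 3) against 9.96 ± 0.02 in controls, 2.47-fold lower, with adjusted p = 0.23 in limma. Arc, an activity-dependent synaptic protein, was 1.62-fold lower (log2 -0.69 ± 0.12), Fos 1.69-fold (-0.75 ± 0.23), Egr2 1.61-fold (-0.69 ± 0.24) and Btg2 1.73-fold (-0.79 ± 0.27). None of these passed over all genes. On all of them the 3 acute arrays lay below the 3 controls, but the rule that named them required this. Of all probe sets tested, 3.56% had groups that did not overlap. Genes of striatal projection neurons were higher, by a median of 0.28 on the log2 scale, in 19 of 19 measured members. This list likewise did not pass in camera with an estimated correlation (adjusted p = 0.318).

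Of the 19 immediate early genes tested, 15 were lower and 4 higher, with a median of -0.30. Adjusted over the list alone 2 passed, Nr4a1 and Arc, against 0 over all genes tested. The list passed in camera (adjusted p = 7.2e-13 with the preset correlation, adjusted p = 0.275 with an estimated correlation), while fry, which tests for 1 direction on balance, did not pass (adjusted p = 0.635) and its mixed form gave 0.0403. In the list of pan striatal projection neurons, Rasd2 was 0.47 ± 0.20 higher and Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, 0.40 ± 0.18 higher. Adjusted over the list alone 0 of its genes passed, and 0 over all genes. Its adjusted p was 7.2e-13 (adjusted p = 0.318 with an estimated correlation), and its median was 0.47 without control 2 (Rasd2 0.74, Ppp1r1b 0.64) and 0.18 without control 3 (Ppp1r1b 0.26). On the single arrays the mean of this list lay at -0.38 on control 1, 0.13 on control 2 and -0.53 on control 3, and between -0.00 and 0.11 on the acute arrays.

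A further 6 lists passed in camera with the preset correlation, and none of them with an estimated one. In each, 0 genes passed over all genes and 0 adjusted over the list alone. The direct-pathway neuron list was higher in 8 of 9 genes (median 0.20, Drd1 0.35 ± 0.17), with adjusted p = 0.0324, and did not pass with the replicate block (adjusted p = 0.0923). Microglial genes were higher in 14 of 16 (median 0.10, Fcrls 0.30 ± 0.17), endothelial, pericyte and meningeal genes in 19 of 21 (0.08, Cldn5 0.41 ± 0.19) and unfolded protein response genes in 16 of 20 (0.07, Hspa5 0.16 ± 0.08). Glucocorticoid response genes were lower in 13 of 17 (median -0.10, Tsc22d3 -0.35 ± 0.15, Nfkbia -0.33 ± 0.14). Genes of thalamus, septum and hypothalamus were lower in 18 of 21, with a median of -0.36, and the mean of that list was 1.01 on control 3 and 0.46 on acute 3 against -0.49 to 0.07 on the rest. With an estimated correlation the adjusted p of these lists was 0.66 for the direct pathway, 0.675 for microglia and for thalamus, septum and hypothalamus, and 0.275 for the other 3. Leaving out a single array ended the call of the direct-pathway list (median 0.08 and adjusted p = 0.8 without control 1, 0.0951 without acute 1, 0.221 without acute 3), and of microglia, which turned to -0.03 (0.8) without control 1 and had 0.0587 without acute 1. Without control 2 these medians were 0.30 and 0.25. Fcrls was 0.17 and 0.48 without control 1 and control 2, Nfkbia -0.21 without control 3 and Cldn5 0.27 without acute 1. Calls also ended for endothelium (median 0.045 and 0.124 without acute 1, 0.175 without acute 3) and the unfolded protein response (0.195 without control 1, 0.106 without control 2, 0.333 without acute 3). Thalamus, septum and hypothalamus turned to 0.03 (0.416) without control 3, and had a median of -0.12 (0.0601) without acute 1 and of -0.22 (0.0726) without acute 2.

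Over all 16335 probe sets, 0 passed in limma, the smallest adjusted p being 0.23, and 139 had an unadjusted p under 0.05, where chance gives 817. At 1.5-fold with an unadjusted p under 0.05 there were 10, of which 1 was higher and 9 lower. With the replicate block 687 had an unadjusted p under 0.05, again below the 817 of chance, and 15 also reached 1.5-fold. The smallest adjusted p was then 0.188. The count of 10 was 61, 57 and 4 without control 1, 2 and 3, and 5 and 52 without acute 1 and acute 3, and that of 139 was 398, 405 and 57 without control 1, 2 and 3 and 86, 72 and 347 without acute 1, 2 and 3. Nr4a1 passed without chronic 1 (adjusted p = 0.00348), or when only the acute and control arrays were fitted (adjusted p = 0.014). The other genes named by rule had an adjusted p of 1. Higher were Kcnj14, a potassium channel, by 1.37-fold, Arpc1b, a subunit of the Arp2/3 complex, by 1.44-fold, Hamp2 by 1.39-fold, Inhba, the activin A subunit, by 1.37-fold, Rasgef1b by 1.41-fold and Coch by 1.43-fold. Lower were Aff2 by 1.31-fold, Nexmif by 1.36-fold and Nmbr, a receptor for neuromedin B, by 1.62-fold. With the tissue covariates Rasgef1b went from 0.49 to 0.29, Coch from 0.52 to 0.30 and Nmbr from -0.70 to -0.46. Without control 3 they were 0.26, 0.29 and -0.34, and Aff2 went from -0.39 to -0.25; Coch was 0.30 without acute 1, and Hamp2 went from 0.48 to 0.29 without control 2.

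At 8 weeks after chronic MPTP, genes of striatal projection neurons were higher than in the 1-week controls. The pan striatal list passed in camera with the preset correlation but not with an estimated one (adjusted p = 0.238). Its median fell from 0.50 to 0.13 with the tissue covariates. Drd2, the dopamine receptor of indirect-pathway neurons, lay at 11.88 ± 0.16 (SD, n = 3) against 11.12 ± 0.35, 1.69-fold higher, and Drd1, that of direct-pathway neurons, was 0.59 ± 0.17 higher on the log2 scale. Sv2c, a synaptic vesicle protein abundant in the basal ganglia, was 1.67-fold higher, and Scn4b, a sodium channel subunit, 0.80 ± 0.30 higher. Most immediate early genes were also higher, among them Nr4a1 by 2.11-fold (1.08 ± 0.16) and Egr2 by 1.01 ± 0.24. Neuronal genes with high levels in cortex were lower, among them Nrn1 (-1.42 ± 0.52) and Cck (-1.19 ± 0.46). The cortex list did not pass in camera with an estimated correlation (adjusted p = 0.741). Its median turned in sign without control 1, the only control array high in cortex genes. None of the genes named here passed over all genes, with adjusted p between 0.876 and 0.898 in limma. With the means of both tissue lists as covariates Drd2 went from 0.76 to 0.48, Drd1 to 0.27, Sv2c from 0.74 to 0.39, Scn4b to 0.18, Nrn1 to -0.33 and Cck to -0.61, while Nr4a1 was 1.25 and Egr2 1.29. Nrn1 and Cck belong to the cortex list, so that covariate holds part of their own values. Scn4b was 1.21 and 0.49 without control 2 and control 3, and Cck -0.77 without control 1.

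The pan striatal list was higher in 19 of 19 genes, with a median of 0.50. Adjusted over the list alone 14 passed, against 0 over all genes; Foxp1 (0.50 ± 0.13), Rarb (0.51 ± 0.14), Rasd2 (0.66 ± 0.20) and Pde7b (0.60 ± 0.18) were the first of them by p. Its camera adjusted p was 2.67e-17 (adjusted p = 0.238 with an estimated correlation), and its genes are co-expressed, with an estimated correlation of 0.65. Direct-pathway genes were higher in 9 of 9 (median 0.58) and 4 passed adjusted over the list alone, Drd1, Slc35d3, Ebf1 and Chrm4. In the indirect-pathway list 8 of 9 were higher (0.23) and Drd2 alone passed so, while in the list of dopamine receptor signalling and plasticity 17 of 24 were higher (0.21) and 3 passed so, Drd2, Rgs2 and Drd1. No gene of these 3 lists passed over all genes, and with an estimated correlation the adjusted p was 0.238, 0.258 and 0.238. The signalling list shares 5 genes with other lists, Drd1, Drd2 and Rgs9 among them, and its median was 0.14 without control 3. The mean of the pan striatal list was 0.17, 0.17 and 0.30 on the chronic arrays, close to the 0.13 of control 2 and above the -0.38 of control 1, which was high in cortex genes, and the -0.53 of control 3, which was high in thalamic and choroid plexus genes. With the means of both tissue lists as covariates the median of the pan striatal list was 0.13 (Foxp1 0.24, Rarb 0.18, Rasd2 0.28, Pde7b 0.17), and it was 0.44 without the 3 arrays high in cortex genes and 0.35 without the 2 high in choroid plexus genes. The covariates also lowered the direct-pathway median to 0.21 (Slc35d3 0.35, Ebf1 0.21, Chrm4 0.34) and that of dopamine signalling to 0.07 (Rgs2 0.25), while the indirect-pathway median was 0.30. With the block added, the signalling list did not pass (adjusted p = 0.116).

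The immediate early gene list was higher in 17 of 19 genes, with a median of 0.49. Fos was little changed, at 0.05 (adjusted p = 0.99 in limma), and 0.51 with the tissue covariates. Btg2 was lower, with a mean of 8.08 against 8.18 in controls. Adjusted over the list alone 9 passed, against 0 over all genes: Nr4a1, Egr2, Arc, Fosl2, Egr3, Fosb, Egr4, Egr1 and Nr4a3. Its adjusted p was 2.68e-11 (adjusted p = 0.238 with an estimated correlation), and fry gave adjusted p = 0.188 and its mixed form 0.139. Circadian clock genes were higher in 16 of 18 by a median of 0.07 (adjusted p = 0.0414, and adjusted p = 0.741 with an estimated correlation), with Usp2 at 0.33 ± 0.12 and Per1 at 0.51 ± 0.27 (0.81 and 0.28 without chronic 1 and chronic 2). Cerebral cortex genes were lower in 14 of 17, with a median of -0.33 (adjusted p = 0.047), and thalamus, septum and hypothalamus genes in 18 of 21, with a median of -0.31 (adjusted p = 0.0413); both had adjusted p = 0.741 with an estimated correlation. In these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. The cortex list turned to 0.02 without control 1 (adjusted p = 0.827), was -0.61 without control 3 and -0.21 (0.134) without chronic 3, and did not pass without acute 1 (0.0508), chronic 1 (0.158) or chronic 2 (0.108). The thalamus, septum and hypothalamus list turned to 0.03 without control 3 (0.919), was -0.58 and -0.50 without control 1 and control 2 and -0.16 without chronic 1 (0.162), and did not pass without chronic 3 (0.134). The clock list turned to -0.00 without control 1 (0.331), was 0.12 and 0.13 without control 2 and control 3 and 0.17 without chronic 1, and did not pass without chronic 2 (0.05, 0.162) or chronic 3 (0.035, 0.319).

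**Figure D2:**
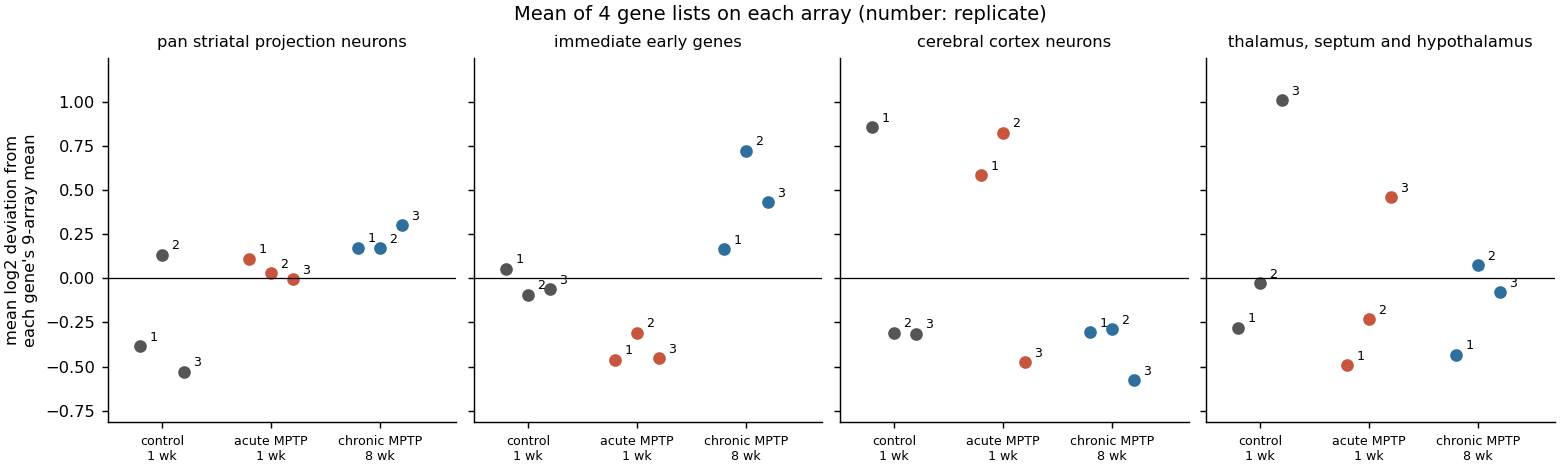
Mean log2 deviation of 4 gene lists from each gene's mean over the 9 arrays, shown for each array by group, with points numbered by replicate. The pan striatal mean is lowest on control 1 and control 3 (-0.38 and -0.53), the cortex mean is highest on control 1, acute 1 and acute 2, and the thalamic mean is highest on control 3; the immediate early gene mean separates acute from chronic arrays.

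Of all 16335 probe sets, 0 passed in limma, with a smallest adjusted p of 0.876, and 900 had an unadjusted p under 0.05, where chance gives 817. At 1.5-fold with an unadjusted p under 0.05 there were 82 higher and 83 lower, 165 in all, and 85 and 122 with the replicate block. In the blocked fit 2128 had an unadjusted p under 0.05, well above the 817 of chance, and 0 passed (smallest adjusted p 0.255). Without chronic 1, Nr4a1 and Egr2 passed, both with adjusted p = 0.00479. The count of 165 was 365 and 80 without control 2 and control 3, 283 and 103 without chronic 2 and chronic 3, 248 without chronic 1, and 56 with the tissue covariates, and that of 900 was 465 without control 3 and 584 without chronic 3. The other genes named by rule all had adjusted p = 0.876. Higher were Onecut2, a homeobox transcription factor, by 1.60-fold, Cdc42ep3, an effector of the GTPase Cdc42, by 1.49-fold, Gpat3, a glycerolipid synthesis enzyme, by 1.40-fold, Bves by 1.44-fold and Zswim6 by 1.62-fold. Lower were Adcyap1, the neuropeptide PACAP, by 2.28-fold, Slc6a7, the brain proline transporter, by 1.88-fold, Plcxd2 by 1.66-fold, Chl1, a neural adhesion molecule, by 1.62-fold, Kcnc4, a potassium channel, by 1.59-fold, Camk1 by 1.57-fold, Rnd1 by 1.39-fold and 1 probe set of Tns1 by 1.39-fold. The brightest probe set of Tns1 had the opposite sign, with means of 8.88 in chronic and 8.75 in control. With the tissue covariates Zswim6 went from 0.70 to 0.37, Cdc42ep3 from 0.57 to 0.37 and Bves from 0.53 to 0.35. Adcyap1 went from -1.19 to -0.63, Kcnc4 from -0.67 to -0.34, Plcxd2 from -0.73 to -0.47, Chl1 from -0.70 to -0.41 and Camk1 from -0.65 to -0.40, while Onecut2 went from 0.68 to 0.76.

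Between the regimens, at equal total dose, Nr4a1 and Arc rose in chronic against acute MPTP. Nr4a1 lay at 11.04 ± 0.36 (SD, n = 3) in the chronic and 8.66 ± 0.07 in the acute group, 5.22-fold higher (log2 2.38 ± 0.16, adjusted p = 0.00131 in limma). Arc lay at 9.96 ± 0.16 against 8.78 ± 0.07, 2.27-fold higher (1.18 ± 0.12, adjusted p = 0.0288), a call that the replicate block ended (adjusted p = 0.0619). Egr2 (1.70 ± 0.24, adjusted p = 0.295), Fosb (1.20 ± 0.24, adjusted p = 0.877), Nr4a3 (1.29 ± 0.34, and 1.94 with the tissue covariates) and Dusp1 (1.26 ± 0.33) were higher without passing over all genes. The acute arrays lay below and the chronic arrays above the controls in Nr4a1, Arc, Egr2 and Fosb.

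**Figure D3:**
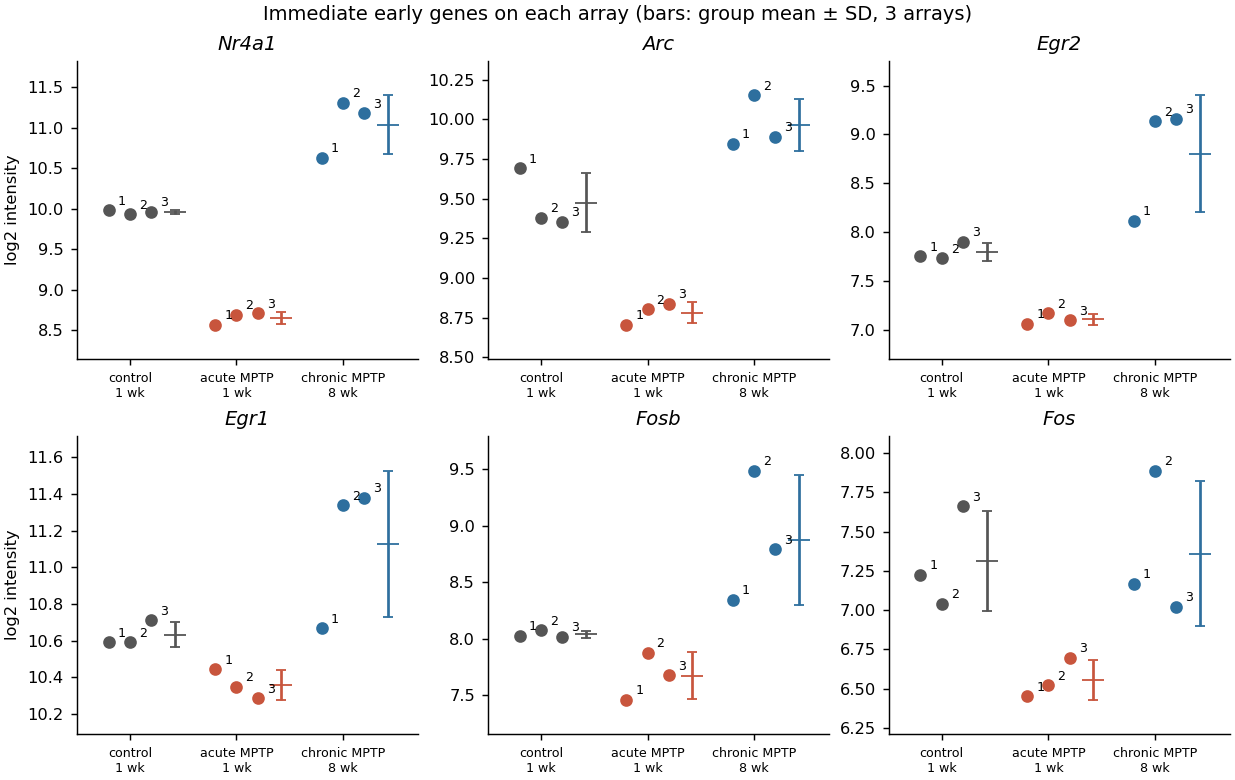
Log2 intensity of 6 immediate early genes on each array, by group, with points numbered by replicate and bars for the group mean ± SD of 3 arrays. For Nr4a1 the acute mean is 8.66, the control mean 9.96 and the chronic mean 11.04, with no overlap between groups.

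The immediate early gene list was higher in 19 of 19 genes, with a median of 0.77. Of these 2 passed over all genes and 13 adjusted over the list alone: Nr4a1, Arc, Egr2, Egr1, Fosb, Junb, Egr4, Dusp1, Nr4a3, Fosl2, Fos, Npas4 and Btg2. Its camera adjusted p was 3.25e-24 (adjusted p = 0.104 with an estimated correlation), fry gave adjusted p = 0.0221 and its mixed form 0.00088. Projection neuron genes were higher too: 9 of 9 of the direct pathway (median 0.29, Sfxn1 0.24 ± 0.10), 9 of 9 of the indirect pathway (0.20, Drd2 0.42 ± 0.16) and 18 of 19 pan striatal genes (0.19, Meis2 0.25 ± 0.11). Of these lists 0 genes passed over all genes and 0 adjusted over the list alone, and their adjusted p with an estimated correlation was 0.43, 0.556 and 0.714. Dopamine receptor signalling genes were higher in 19 of 24 (0.14), where Rgs2, a regulator of G protein signalling, passed adjusted over the list alone (0.59 ± 0.10) and 0 passed over all genes (adjusted p = 0.43 with an estimated correlation). Without acute 3 and chronic 3 the indirect-pathway median was 0.31 and 0.12 and that of dopamine signalling 0.09 and 0.08, and the indirect-pathway list did not pass without chronic 2 (0.0516). With the tissue covariates the medians were 0.01, 0.05, -0.09 and 0.05 for these 4 lists, with Drd2 at 0.16 and Meis2 at 0.09. Of these the pan striatal list passed with the opposite sign (adjusted p = 0.0356) and the others did not pass (0.463, 0.213 and 0.0698). The immediate early gene median was then 1.12.

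Glucocorticoid response genes were higher in 14 of 17 (median 0.15, Klf9 0.28 ± 0.10) and clock genes in 12 of 18 (0.15, Per1 0.72 ± 0.27). Cerebral cortex genes were lower in 15 of 17, with a median of -0.55 (Cck -1.52 ± 0.46, Nrn1 -1.66 ± 0.52), and complex I genes in 22 of 34, with a median of -0.09. In these 4 lists 0 genes passed over all genes and 0 adjusted over the list alone. Their camera adjusted p was 0.00683, 0.0154, 0.00228 and 0.049, and with an estimated correlation the adjusted p was 0.465, 0.702, 0.579 and 0.714. The cortex median was -0.32 without acute 1, -0.27 without acute 2, -1.03 without acute 3 and 0.01 without the 3 arrays high in cortex genes. With the tissue covariates, of which the cortex mean includes both genes, Cck was -0.70 and Nrn1 -0.51. The glucocorticoid median was 0.08 (0.262) without chronic 1, 0.10 without acute 2 and 0.09 without chronic 3. The clock median was 0.26 without chronic 1, and the list did not pass without acute 1 (0.07, 0.0921), chronic 2 (0.08, 0.123) or chronic 3 (0.04, 0.133). The call of complex I, whose median was -0.15 without chronic 1, ended without control 2 (0.0502), acute 1 (0.11), acute 3 (0.0706), chronic 2 (-0.06, 0.781) or chronic 3 (0.0578).

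**Figure D4:**
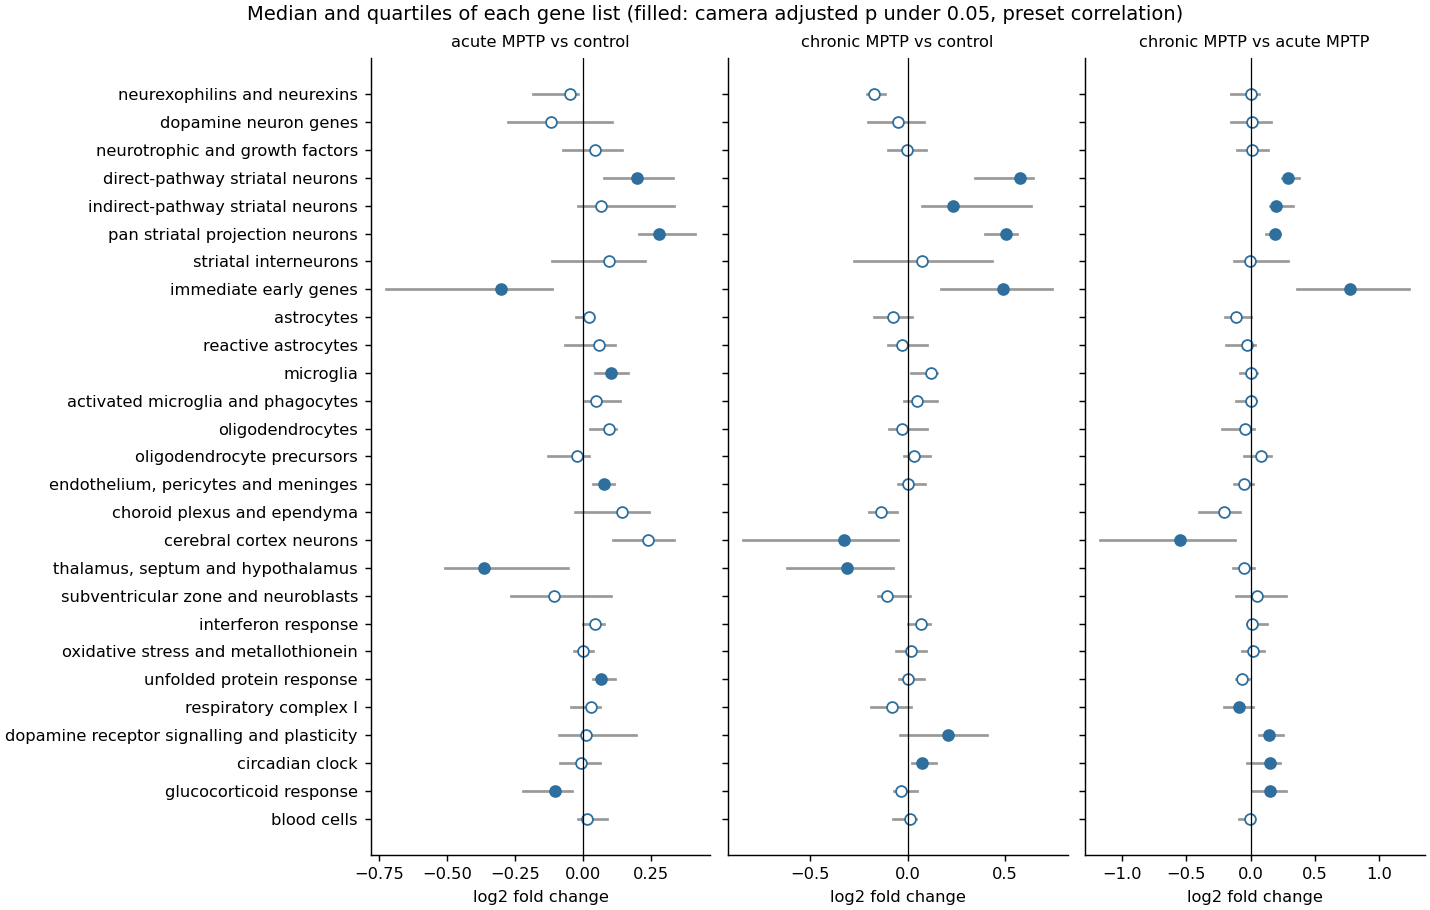
Median log2 fold change (points) and quartiles (lines) of the members of each of the 27 gene lists in the 3 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation. Immediate early genes lie at -0.30 in acute against control, 0.49 in chronic against control and 0.77 in chronic against acute MPTP, and 0 lists passed with an estimated correlation.

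In limma 2 of 16335 probe sets passed, both higher, and 837 had an unadjusted p under 0.05, where chance gives 817. At 1.5-fold with an unadjusted p under 0.05 there were 45 higher and 42 lower. With the replicate block 2278 had an unadjusted p under 0.05, well above the 817 of chance. Of the probe sets 2 then passed, Nr4a1 (adjusted p = 0.00209) and Tiparp (adjusted p = 0.0338), while Arc did not. Nr4a1 passed with any single array left out (adjusted p between 3.59e-05 and 0.0247). It did not pass without the 2 arrays high in choroid plexus genes (2.41, adjusted p = 0.0755) or with the tissue covariates (2.50, adjusted p = 0.0527). Without the 3 arrays high in cortex genes, which leaves 1 acute array, its log2 difference was 2.33. Arc did not pass without control 2 (0.0863), control 3 (0.0657), acute 1 (0.265), acute 2 (0.254), acute 3 (0.128), chronic 2 (0.103) or chronic 3 (0.203). With the tissue covariates its adjusted p was 0.39 in limma, and in all Arc kept its call in 7 of 21 alternatives. Without chronic 1, 5 passed, and the count of 87 at 1.5-fold was 196, against 139 without chronic 2, 56 without chronic 3 and 182 without acute 3. The count of 837 was 1382 without chronic 1, 503 without chronic 3 and 390 without acute 2. The other genes named by rule did not pass, with adjusted p between 0.618 and 0.877. Higher were Tiparp, an aryl hydrocarbon receptor target, by 1.96-fold, Onecut2 by 1.56-fold and Cdc42ep3, by 0.59 ± 0.11 on the log2 scale. Lower were Slc6a7 by 1.67-fold, Camk1 by 1.47-fold, Casr, the calcium-sensing receptor, by 1.43-fold, Thsd7b by 1.41-fold, Gsn, the actin-severing protein gelsolin, by 1.38-fold, 1 probe set of Tns1 by 1.38-fold, Adap1 by 1.36-fold and Czib by 1.31-fold. The brightest probe set of Tns1 had the opposite sign, with means of 8.88 in chronic and 8.85 in acute. With the tissue covariates Camk1 went from -0.56 to -0.33 and Thsd7b from -0.49 to -0.31.

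Both MPTP groups were compared with the same 3 controls, which alone makes their fold changes alike. Across the 16335 probe sets, which are not independent replicates, the log2 fold changes of acute and chronic MPTP against control correlated with r = 0.386, where unchanged groups simulated against shared controls gave 0.499, and 59.6% had the same sign against a simulated 66.7%. That simulated noise ignored the pairing by replicate number. Noise with the spread of the fit with the replicate block gave the same 0.499 and 66.7%. The covariance was 0.00891. It lay below the simulated 0.0126 (difference -0.0037) where the noise ignored the pairing by replicate number, and above the simulated 0.00618 (difference 0.00273) where the noise had the spread of the fit with the replicate block. Of the 68 and 466 probe sets higher at an unadjusted p under 0.05, 16 were shared, and of the 71 and 434 lower, 12 were shared. Simulated lists of the same lengths shared 21.7 and 21.5, and independent lists 1.94 and 1.89. The simulations drew each probe set independently. The 3 controls are too few to be split, so part or all of the sharing may come from them.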

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

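The fits with tissue list means as covariates, and those without the arrays high in cortex or choroid plexus genes, were tests chosen only after the data had been seen. By the test of the difference between acute and chronic MPTP itself, 2 genes passed in limma and 9 gene lists in camera with the preset correlation. None of these lists passed with an estimated one. The log2 difference, chronic minus acute, was 2.38 for Nr4a1 and 1.18 for Arc. The call of Arc ended, among others, with the replicate block (adjusted p = 0.0619) and without control 2, control 3, acute 1, acute 2, acute 3, chronic 2 or chronic 3 (adjusted p from 0.0657 to 0.265). In all, Arc kept its call in 7 of 21 alternatives. The medians of the lists were 0.77 for immediate early genes, 0.29 for direct-pathway neurons, 0.20 for indirect-pathway neurons, 0.19 for pan striatal neurons and 0.14 for dopamine receptor signalling. They were 0.15 for clock genes, 0.15 for glucocorticoid response genes, -0.093 for complex I and -0.55 for cerebral cortex genes. None of the 9 lists passed with an estimated correlation, where the smallest adjusted p was 0.104, and with the tissue covariates the pan striatal list passed with the opposite sign, at -0.092 (adjusted p = 0.0356). Groups of 3 arrays were not tested for outlying arrays.

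Immediate early genes were higher on all 3 chronic than on all 3 acute arrays, with list means from 0.17 to 0.72 against -0.46 to -0.31. Tissue from cortex, thalamus, septum or hypothalamus is argued against as the whole cause, since the median was 1.12 with both tissue list means as covariates (list mean 1.04, 95% interval 0.50 to 1.58, against 0.85, 0.50 to 1.20, without). The median was 0.78 after quantile normalization, which cannot decide on array-wide scaling, since the quartiles of the deposited arrays were already alike. A different time of day at killing stays open, because the score of 7 clock output genes minus Arntl differed by 0.27 with a 95% interval from -0.21 to 0.76. That difference rests largely on acute 1, which scored 0.997. Acute 2 and acute 3 scored 1.56 and 1.65, within the chronic range of 1.51 to 1.87. Regimen and time since dosing stay open as biological explanations, and were not tested apart, since they differ together between these groups.

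Pan striatal genes were higher on the chronic than on the control arrays, by a median of 0.50. The median was 0.52 after quantile normalization, which cannot decide on array-wide scaling, since the quartiles of the deposited arrays were already alike. Tissue from cortex, thalamus, septum or hypothalamus on some control arrays may account for much of the difference, by a covariate fit with 4 residual degrees of freedom. With both tissue list means as covariates the median was 0.13, 26.0% of the value without them. Yet acute 1 and acute 2 had cortex list means of 0.59 and 0.83, near the 0.855 of control 1. Their pan striatal means were 0.11 and 0.03 against its -0.38. Acute 3, at 0.46 in the thalamus, septum and hypothalamus list, had -0.00, while control 3, at 1.01, had -0.53. Tissue content alone therefore did not set the level of these genes on the acute arrays. The difference of list means went from 0.47 (95% interval 0.06 to 0.89) to 0.12 (-0.34 to 0.57), an interval that still includes 0.47, and the median was 0.44 without the 3 arrays high in cortex genes and 0.35 without the 2 high in choroid plexus genes. A biological change with regimen or time since dosing therefore stays open, and was not tested.

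The 6 arrays of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. For acute MPTP against control, 10, 8 and 5 of the 10 splits gave as many probe sets past the threshold, as many at 1.5-fold and as many lists. The real values were 0, 10 and 8, and the highest of the others 101, 422 and 17. The split of control 1, acute 1 and acute 2 from the rest gave the 101, which points to a structure of the samples, since these are the arrays high in cortex genes. For chronic MPTP against control the numbers were 10, 4 and 5, with real values of 0, 165 and 8 and highest others of 0, 228 and 13. For chronic against acute MPTP they were 1, 4 and 2, with real values of 2, 87 and 9 and highest others of 0, 191 and 11. In each comparison 3 other splits also part all 3 same-numbered pairs. Those gave 3, 34 and 4 probe sets at 1.5-fold for acute against control, 3, 195 and 12 for chronic against control and 13, 2 and 6 for chronic against acute MPTP, and 0 past the threshold. Their lists numbered 0, 17 and 10, then 8, 11 and 13, then 5, 5 and 11. The remaining splits part 1 pair each.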

How the results depend on the processing

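The tests with tissue list covariates (without and with the replicate block), without the 3 arrays high in cortex genes and without the 2 high in choroid plexus genes were chosen after the data were seen. Of 6026 comparisons of 290 gene results with an alternative, 5899 kept direction and side of the threshold, 17 lost a call, 7 gained one, 0 reversed and 103 changed sign without a call. Of 1845 for 81 list results the numbers were 1486, 90, 79, 17 and 173. Only 2 of the gene results passed in the main fit, Nr4a1 and Arc in chronic against acute MPTP, so the others had no call to lose. Arc kept its call in 7 of 21 alternatives. Quantile normalization, median centring, the 50th percentile filter, the trended variance model and an adjusted p under 0.10 left the counts of probe sets past the threshold, of those at 1.5-fold and of lists within 1.5 times. No depth is defined for arrays, and signal over background is not given in the sources used here. Except where the construction shows it (fewer arrays or more probe sets tested), the cause of a change was not tested.

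Without the filter 1 probe set passed in chronic against acute MPTP. With only the 2 groups compared 1 passed in acute against control (Nr4a1) and 1 in chronic against acute MPTP. Array weights gave 18 probe sets at 1.5-fold in acute and 82 in chronic against control, and 5 lists in chronic against control, and put Nxph3 at 0.56 in acute and -0.14 in chronic against control. With an estimated correlation 0, 0 and 0 lists passed in the 3 comparisons. Counts at an unadjusted p under 0.05, which were 139, 900 and 837 in the 3 comparisons, moved further: acute against control had 286 without the filter, 60 with the 50th percentile filter and 345 with array weights. Chronic against control had 592 with array weights, and chronic against acute MPTP 530 with the 50th percentile filter. With tissue covariates the 2 comparisons of chronic MPTP had 248 and 401, with the block added all 3 had 1081, 1478 and 1838, without the cortex-high arrays chronic MPTP had 536 and 342, and without the choroid-high arrays 394 against control. With each array left out they ran from 57 to 405, 465 to 1289 and 390 to 1382. With the replicate block 687, 2128 and 2278 probe sets had an unadjusted p under 0.05, where chance gives 817. The median standard error was 0.125 without and 0.089 with the block. The block ended the calls of Arc (adjusted p = 0.0619) and of the direct-pathway list in acute against control (adjusted p = 0.0923) and added Tiparp (adjusted p = 0.0338); it changed no other call of a named gene or list.

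With tissue covariates chronic against control had 56 probe sets at 1.5-fold. Nxph3 was 0.14 in chronic against control and 0.11 in chronic against acute MPTP. The medians in chronic against control were -0.095 for microglia, -0.37 for oligodendrocytes and 0.27 for the subventricular zone. In chronic against acute MPTP 0 probe sets passed, with medians of 0.11 for neurexophilins and neurexins and -0.092 for pan striatal genes. With the block added, Nxph3 was -0.023, 0.12 and 0.14 in the 3 comparisons, and probe sets at 1.5-fold numbered 23, 104 and 134, with 1 past the threshold in chronic against acute MPTP. The medians were then -0.12 for microglia, -0.36 for oligodendrocytes and 0.28 for the subventricular zone in chronic against control, and -0.11 for pan striatal genes in chronic against acute MPTP.

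Without the 3 arrays high in cortex genes, which leaves 1 acute array assumed to vary like the others, Nxph3 was -0.13, 0.13 and 0.26. Acute against control had 31 probe sets at 1.5-fold and a microglia median of -0.056, and chronic against acute MPTP had 0 past the threshold and a cortex median of 0.013. Without the 2 arrays high in choroid plexus genes, chronic against control had 85 at 1.5-fold and a thalamus, septum and hypothalamus median of 0.025. Chronic against acute MPTP then had 0 past the threshold, 185 at 1.5-fold and a choroid plexus median of 0.28, and Nxph3 was 0.49, -0.57 and -1.06 in the 3 comparisons.

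With each array left out in turn, acute against control had 0 to 1 probe sets past the threshold, 4 to 61 at 1.5-fold and 7 to 13 lists. Chronic against control had 0 to 2, 80 to 365 and 5 to 11, and chronic against acute MPTP 1 to 5, 56 to 196 and 6 to 14. Nxph3 ran from 0.03 to 0.75 in acute against control, -0.57 to 0.13 in chronic against control and -1.06 to -0.34 in chronic against acute MPTP. In acute against control the medians ran from -0.028 to 0.25 for microglia, -0.37 to 0.35 for choroid plexus and -0.52 to 0.025 for thalamus, septum and hypothalamus, and the last ran from -0.58 to 0.025 in chronic against control.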

Other observations

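The slope of Nxph3 on the cortex list mean and its correlation among 6 arrays were tests chosen only after the result was seen. Genes of dopamine neurons did not pass as a list in any of the 3 comparisons, nor with any single array left out. The arrays measured striatal tissue, which these neurons reach by their axons, so the list cannot decide whether MPTP harmed the neurons. Of 12 genes tested, 7 were lower in acute and 7 in chronic against control (medians -0.12 and -0.05). In chronic against acute MPTP 6 were lower (median 0.01, mean -0.03, test up). The acute median was -0.01 without control 2 and -0.05 without control 3 or acute 1, and the chronic one turned to 0.02 without control 3 or chronic 3. Slc6a3, the dopamine transporter, had a log2 fold change of -0.27 ± 0.10 in acute against control, and Slc18a2, the vesicular monoamine transporter, -0.55 ± 0.27 in chronic against control. In the other comparison with control the means lay closer, at 6.56 in chronic against 6.64 for Slc6a3 and 6.62 in acute against 6.90 for Slc18a2. Th, tyrosine hydroxylase, lay at -0.21 ± 0.39 in acute and 0.17 ± 0.39 in chronic against control, and Ddc at -0.26 ± 0.23 and -0.12 ± 0.23. None of these 4 passed over all genes or adjusted over the list alone. Slc18a2 and Ddc were highest on control 3 and acute 3, the arrays highest in Slc17a6, while Th and Slc6a3 did not share this order. Slc18a2 was -0.31 without control 3 and -0.09 with the tissue covariates. Th ran from -0.63 without control 1 to 0.06 without control 2 in acute and from -0.25 without control 1 to 0.50 without chronic 1 in chronic against control. Ddc ran from -0.49 without acute 3 to -0.06 without control 3, and from -0.32 without control 1 to 0.08 without control 3. In the interneuron list 8 of 15 genes were higher in chronic against control (median 0.08), and 1 passed adjusted over the list alone, Kit, at 0.51 ± 0.13, against 0 over all genes; Kit was 0.32 with the tissue covariates and 0.26 with the block added. In camera with the preset correlation this list passed without control 2 (median 0.11, adjusted p = 0.00648) or control 3 (0.18, 0.0355), and in acute against control likewise (0.19, 0.00919 and 0.17, 0.0422). Its medians in acute against control and chronic against acute MPTP were 0.10 (mean -0.02) and -0.00 (mean 0.06), with a test up in both. The neuropeptide genes Penk, Tac1 and Pdyn had 0.23 ± 0.10, 0.58 ± 0.25 and 0.34 ± 0.29 in chronic against control, and none passed over all genes. With the tissue covariates Penk was -0.02 and Tac1 0.03. Tac1 was 0.35 without control 3, and Pdyn 0.04, 0.53, 0.52 and 0.09 without control 1, control 2, chronic 1 and chronic 2.

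Glial and inflammatory lists not named above did not pass in the 3 comparisons, and in none of them did a gene pass adjusted over the list alone or over all genes. Medians for acute against control, chronic against control and chronic against acute MPTP were 0.02, -0.07 and -0.11 for astrocytes and 0.06, -0.03 and -0.03 for reactive astrocytes (test up in chronic against control). Gfap, the astrocyte filament protein, lay at 0.11 ± 0.22, -0.27 ± 0.22 and -0.38 ± 0.22. Medians were 0.05, 0.05 and 0.00 for activated microglia and phagocytes, where the last had a mean of -0.00 and a test up. Aif1, a microglial protein, lay at 0.13 ± 0.10 and 0.15 ± 0.10 against control. Oligodendrocytes had 0.10, -0.03 and -0.05 (test up in chronic against control), their precursors -0.02, 0.03 and 0.08, and interferon response genes 0.05, 0.07 and 0.01. With the tissue covariates the oligodendrocyte median in chronic against control was much lower, as given with the other alternatives above. Leaving out 1 array made calls. In acute against control, median and adjusted p were 0.07 and 0.0381 for astrocytes without acute 2, 0.13 and 1.31e-05 for reactive astrocytes without control 3 (0.08, 0.0145 without acute 1), -0.13 and 0.00376 for oligodendrocyte precursors without control 1, and 0.08 and 0.034 for the interferon response without acute 1. Oligodendrocytes had 0.13 and 0.00362 without control 3 and 0.18 and 9.33e-05 without acute 2, and activated microglia 0.09 and 0.00333 without control 2, 0.12 and 0.000653 without control 3 and 0.06 and 0.0286 without acute 2. In chronic against control activated microglia passed without control 2 (0.08, 0.0224) or control 3 (0.07, 0.0268), and oligodendrocytes without chronic 2 (0.18, 0.00491). Without acute 2, astrocytes (-0.16, 0.0159) and oligodendrocytes (-0.21, 0.0148) passed in chronic against acute MPTP. Without control 3, Gfap was 0.28 and -0.10 and Aif1 0.04 and 0.06 in acute and chronic against control; without control 1, Gfap was -0.10 and -0.48.

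The other lists that did not pass in any comparison had medians, in the same order, of 0.05, -0.00 and 0.01 for neurotrophic and growth factors (mean 0.05 in chronic against control), 0.15, -0.14 and -0.21 for choroid plexus and ependyma, and -0.11, -0.10 and 0.05 for the subventricular zone. The subventricular zone median in chronic against control turned in sign with the tissue covariates. Oxidative stress genes had 0.00, 0.02 and 0.02 (mean -0.01 in acute against control), blood cell genes 0.02, 0.01 and -0.00 (mean -0.01 and test up in chronic against control), and neurexophilins and neurexins -0.05, -0.17 and 0.00 (mean -0.11 and test down in the last). Among lists that passed elsewhere, glucocorticoid response genes had -0.04 with a test up in chronic against control, and microglial genes 0.00 with a mean of -0.02 and a test down in chronic against acute MPTP. The calls that follow also came from camera with the preset correlation. The estimated correlation was 0.62 for choroid plexus, 0.44 for the subventricular zone and -0.003 for growth factors. The choroid plexus list passed in acute against control without control 3 (median 0.35, adjusted p = 0.00362) or acute 1 (0.35, 8.76e-05), and with the opposite sign without acute 3 (-0.37, 0.000247). In chronic against acute MPTP it passed without acute 1 (-0.53, 0.00012) or acute 2 (-0.38, 0.0148), and turned to 0.24 without acute 3. The subventricular zone list passed without acute 2 in acute against control (-0.26, 0.0031) and in chronic against acute MPTP (0.15, 0.0194), and growth factors without control 3 in acute against control (0.04, 0.0438).

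Nxph3 was higher on control 1, acute 1 and acute 2 than on the other 6 arrays, and these are the arrays high in Tbr1 and Slc17a7. The range of Nxph3 over the 9 arrays after quantile normalization was 103% of the deposited range. The quartiles of the deposited arrays were already alike, so this step could move values little and cannot decide on array-wide scaling. Cerebral cortex tissue in the dissected samples is a candidate explanation: with group as a term, Nxph3 had a slope of 1.11 on the cortex list mean (95% interval 0.93 to 1.28), at the 99.8th percentile of 14880 genes. The arrays high in Nxph3 are also those high in the cortex list, so a positive slope largely restates that overlap and is not a separate test. Among the 6 arrays low in cortex genes Pearson's r was 0.492 (exact permutation p = 0.292) and Spearman's rho 0.829 (exact permutation p = 0.0583), and the r of 0.945 without the 2 arrays farthest from the median rests on 4 arrays with cortex list means from -0.31 to -0.29, too narrow a range to bear on the explanation. Of the 17 cortex genes 16 lay at or above the filter on those 6 arrays; whether that signal came from striatum or from cortex tissue was not tested, and neither was any biological explanation.

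Outside the tested set lay 12480 probe sets, with several symbols, with none or under the filter. In limma 0 of them passed in each comparison, and 265, 375 and 472 had an unadjusted p under 0.05 in acute against control, chronic against control and chronic against acute MPTP, where chance gives 624. The smallest adjusted p were 0.0699, 0.957 and 0.248.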
